A study of Mus musculus with 5 samples.

How the data were processed

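Gene expression was measured in cartilage of the mandibular condyle, the joint head of the lower jaw, of mice of a single strain. The series holds 5 arrays of total RNA, 2 from mice without discoidin domain receptor 1 (Ddr1 knockout) and 3 from wild-type mice. Per the labels, RNA was taken directly from the tissue, labelled with biotin and hybridised to the Affymetrix mouse gene 1.0 ST array, whose probes lie along the whole transcript. The label of each array names a mouse of its own and says no more about the animals. Where values differ within a group, the p-values rest on the spread between these mice and their arrays together. Where arrays have identical values, as described below, the p-values do not measure the spread between mice.

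The deposited table holds log2 values made by the authors. Per the submitters' processing notes, these were computed with Affymetrix Expression Console and RMA, which corrects background, quantile-normalises the arrays and summarises the probes of each transcript by median polish. The versions and the genome build are not given in the sources used here. The table has 35556 rows and no column without a sample. Values ran from 0.413 to 13.5 on the log2 scale, with medians over all rows from 4.97 to 5.03.

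Rows were named from the platform's annotation table, with symbols checked by gene identifier against the GRCm38.p6 gene table, where 19856 of the genes tested matched. Of the rows, 21789 had 1 gene symbol, 1621 had several and 12146 had none. Rows with several symbols or none were left out of the main test. The 999 genes with more than 1 row were represented by the row with the highest mean over the 5 arrays, which left 19938 genes. Rows of a gene can disagree, and their mean was an alternative. No coordinates are printed, because the build behind the table is not stated.

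Median polish works on medians and can return exactly the same value for several arrays even where their probes differ. Identical values therefore do not show equal expression. In 17403 genes, 87.3% of those tested, at least 2 of the 5 arrays had identical values as deposited. The 3 wild-type values were identical in 7793 genes and all 5 values in 1249. Such genes enter the fit with a spread of 0 within a group, which limma replaces by a moderated one.

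Genotypes were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on the log2 values of all 5 arrays, with knockout minus wild type as the contrast, two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The array run, 1 or 2, was read from the array names in the labels. Run 1 holds knockout 2 and wild type 3, and run 2 holds knockout 5 and wild types 4 and 6. The run entered as a fixed block in an alternative fit, and differences within each run were computed without a test. The groups share no replicate number, so no pairing was used.

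The 36 gene lists were drawn from textbook knowledge of condylar cartilage, its neighbouring tissues and osteoarthritis. Of 809 list places, 748 were measured, by 713 different genes. Lists were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were given beside it. Fry asks whether the genes of a list move 1 way on balance and does not compare them with other genes. A list member without a named row of its own, such as Runx2 or Bglap, was not analysed here.

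Genes named in the text followed a fixed rule. It took the list on Ddr1 and osteoarthritis, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, up to 3 genes of lowest p from each list, and any gene singled out later. Predicted genes, numbered transcripts, receptor genes of smell and pheromone sensing, microRNAs and small nucleolar RNAs were left out of the largest changes. The groups, main test, lists, naming rule and most alternatives were chosen before the data were examined. Cyclic loess, arrays centred and scaled, and the restrictions on genes with identical values were added after seeing the data.

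The alternatives covered the array run, filters on dim genes, the rows tested, the variance model, array weights, normalisation, the test, the threshold and each array left out in turn. With a single array left in an arm, its spread was taken to be that of the other group. The 10 splits of the 5 arrays into groups of 2 and 3 were fitted in the same way. The 1194 olfactory and vomeronasal receptor genes (names beginning Olfr or Vmn), whose transcripts belong to sensory neurons, were followed as a group, which was chosen after the data were seen. Level-matched random lists drew each gene from the 100 neighbours on each side in wild-type level, 10000 times.

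The fit was tested on simulated data for the knockout against wild-type comparison of 2 against 3 arrays, on 19938 genes with 200 of them changed. It recovered 57.0% of the 2-fold changes (1 on the log2 scale) and 84.0% of the changes of 2 on the log2 scale, with 5 false calls. With no change simulated it made 0 calls in limma, and 21 genes reached an unadjusted p under 0.001. The simulated noise was independent between genes, held no identical values and had the same spread in both groups. In the real table many values are identical. The knockout arrays there differed with a standard deviation over genes of 0.545, and wild-type pairs with at most 0.182. The simulated counts therefore do not measure false calls among the real genes. The precision of every value is limited by the number of arrays. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.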

Results

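The arrays compared mandibular condyle cartilage of Ddr1 knockout mice (n = 2) with that of wild-type mice (n = 3). Ddr1 encodes a receptor tyrosine kinase that binds collagen, and its loss in mice has been studied as a model of osteoarthritis in the jaw joint. The question was which transcripts differ in this cartilage when the receptor is missing. Mice are called by the numbers of their labels, knockout 2 and 5 and wild type 3, 4 and 6. Knockout 2 and wild type 3 were in array run 1 and the others in run 2. Levels are log2 RMA signals, and changes are knockout minus wild type on that scale.

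Ddr1 itself was measured at 5.96 in knockout 2 and 5.80 in knockout 5, and at 6.02 in each of the 3 wild-type mice. The change was -0.14 (SE 0.058), with limma's adjusted p = 0.377, so the deleted gene did not pass the test. It was -0.15 with the run as a block (adjusted p = 0.333), -0.053 within run 1 and -0.22 within run 2. Its sign turned under scalings, to 0.011 with quantile normalisation, 0.035 with cyclic loess and 0.083 with arrays centred and scaled. Without knockout 2 or knockout 5 the adjusted p was 1.4e-06 or 1.7e-05, with the spread of the lone knockout array taken from wild type, where Ddr1 had a spread of 0. Ddr2, the related collagen receptor, had the same value of 5.52 on all 5 arrays. The array's probes cover the whole transcript and their positions were not used here, so a signal from the part left in the knockout cannot be set apart, and Ddr1 does not check the labels.

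Among the 13 measured genes tied to Ddr1 and osteoarthritis, 1 fell and 12 did not pass the test. Sox9, the transcription factor that sets chondrocyte identity, fell from 6.02 ± 0.0051 (SD, n = 3) to 5.60 ± 0.051 (SD, n = 2). The change was -0.42 (SE 0.029, limma's adjusted p = 0.0229), with both knockout mice below all wild-type mice. Its 3 wild-type arrays held only 2 distinct values, so the wild-type SD and the SE do not measure the spread between mice. Col2a1, the main fibrillar collagen of cartilage, was at 7.07 and 6.96 in knockout and 7.27 in each wild-type mouse, a change of -0.26 (adjusted p = 0.069) that turned to 0.045 after cyclic loess. Acan, the large cartilage proteoglycan, went apart between the knockout mice, at 4.81 in knockout 2 and 5.92 in knockout 5 against 5.40 in each wild-type mouse. Col10a1, the collagen of hypertrophic chondrocytes, had a change of 0.34 (adjusted p = 0.416), and Col1a1, the collagen of bone and fibrous tissue, had -0.46 (adjusted p = 0.342). Col1a1 was at 6.53 in knockout 2 and 7.07 in knockout 5 against 7.26 to 7.27 in wild type, so its change was -0.73 within run 1 and -0.19 within run 2, and -0.17 after cyclic loess. The collagenase Mmp13 was at 5.38 in knockout 2 and in every wild-type mouse and at 5.15 in knockout 5, and the aggrecanase Adamts5 had a change of -0.52 (adjusted p = 0.402). Vegfa, an angiogenic growth factor, was at 7.19 in knockout 2 and 6.13 in knockout 5, with wild-type values from 6.16 to 6.26. Itga1 was the same on all arrays, and Itgb1 and Il1b were at -0.066 and -0.057 without passing the test. In wild-type level, Acan, Mmp13, Col10a1 and Adamts5 lay at the 60.7th, 59.8th, 58.1st and 48.1st percentile of all genes. Col2a1 and Col1a1 lay at the 98.9th. No call of detection above background was used here, so how well these genes were detected is open.

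For Sox9 the change was -0.42 with the run as a block (adjusted p = 0.0603), -0.45 within run 1 and -0.39 within run 2, and cyclic loess between the arrays left -0.26 (adjusted p = 0.116). Without wild type 3, 4 or 6 its adjusted p was 0.134, 0.162 and 0.189. Counted over this list alone, adjusted over the list alone, 2 genes fell. The list's camera test gave adjusted p = 0.202, or adjusted p = 0.625 with an estimated correlation, while fry gave adjusted p = 0.003.

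**Figure D1:**
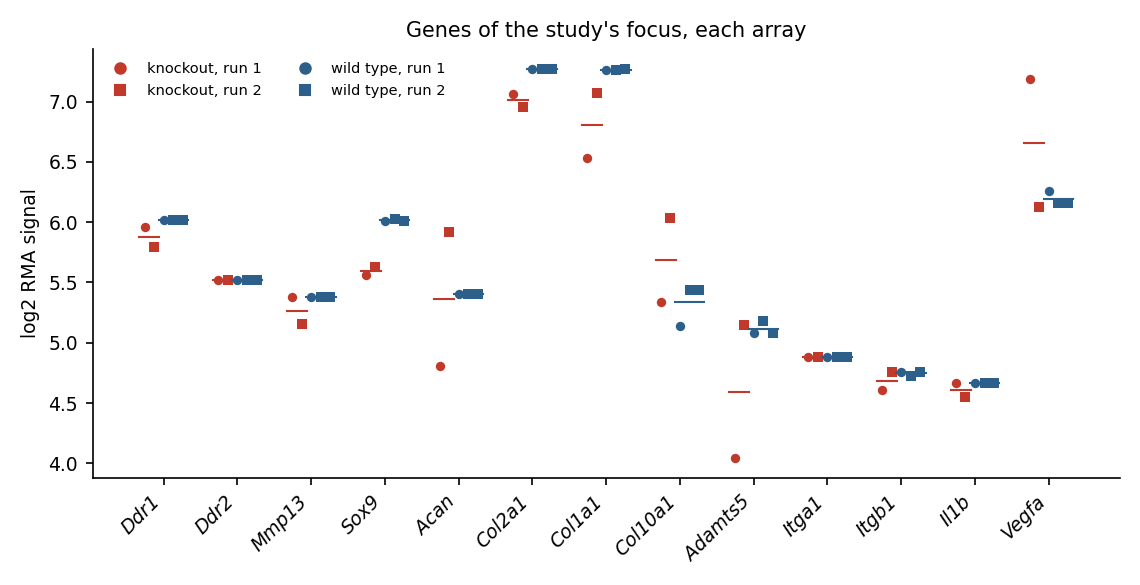
Log2 RMA signal of 13 genes tied to Ddr1 and osteoarthritis on each array, with red for knockout and blue for wild type, circles for run 1 and squares for run 2, and short lines for group means. Sox9 lies at 5.56 and 5.63 in knockout against 6.01 to 6.02 in wild type.

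Over all genes, 309 rose and 435 fell in knockout cartilage at adjusted p under 0.05, 3.73% of the 19938 tested, and 54 of the rises and 49 of the falls were at least 2-fold. Macrod2, an enzyme that removes ADP-ribose from proteins, had the largest fall named by rule, from 9.11 to 6.52 (-2.59, SE 0.169, adjusted p = 0.0217), but in 1 of its 6 rows on the array, and the others ranged from -0.29 to 0.63. Teddm3, a gene of the transmembrane epididymal family, had the largest rise, from 2.72 to 5.49 (2.77, SE 0.323, adjusted p = 0.045), and its adjusted p without knockout 2 was 0.0606. Gipc3, a protein needed for hearing, fell from 6.97 to 5.14 (-1.84, SE 0.179, adjusted p = 0.0346).

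The other 11 large falls ranged from -1.998 for Lamtor1, a lysosomal scaffold of mTORC1 signalling, to -1.27 for the homeobox gene Otx1. They held Gipc3, the testis profilin Pfn3 (-1.60), the phosphatase Lhpp (-1.57), the mitochondrial import subunit Timm13 (-1.55), Carhsp1 (-1.47), Rex1bd (-1.40), Nicn1 (-1.38), the replication licensing factor Cdc6 (-1.30) and the scramblase Plscr1 (-1.29). Wild-type levels of these 12 genes ran from 5.70 for Rex1bd to 9.11 for Macrod2.

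The other 11 large rises ranged from 1.98 for the zinc finger gene Zfp345 to 1.10 for Vwa3b. They held the seminal vesicle protein Svs3a (1.85), the ciliary dynein assembly factor Dnaaf6 (1.67), the 5S ribosomal RNA gene n-R5s136 (1.55), BC061237, Zfp640 (1.35), the pseudogene Tes3-ps (1.33), BC048594 (1.22), the secreted gut protein Retnlb (1.14) and the meiotic protein Sycp3 (1.13). Wild-type signals were 1.37 for Zfp345 and 2.88 for Svs3a, and 7.44 for n-R5s136 and 6.55 for Vwa3b. No call of detection above background was used here, so these folds do not show that the genes were expressed in the tissue. After cyclic loess all 24 genes kept their direction, none passed (lowest adjusted p = 0.052), and 3 had changes smaller by over 1.5 times, Tes3-ps (0.83), BC048594 (0.74) and Sycp3 (0.70).

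Of these 24 genes, 6 had more than 1 row on the array, and the tested row was the brightest. With the rows of a gene averaged, Lamtor1 kept a change of -1.38 (adjusted p = 0.0464). The other 5 no longer passed, at -0.25 for Macrod2 (adjusted p = 0.0913), -0.59 for Carhsp1 (adjusted p = 0.0665), -0.59 for Plscr1 (adjusted p = 0.0528), 0.049 for Vwa3b (adjusted p = 0.638) and 1.55 for Zfp640 (adjusted p = 0.0606). The second rows of Carhsp1 and Plscr1 went the other way, with 0.29 and 0.10.

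All 744 genes past the threshold had groups that did not overlap. No overlap was seen in 6286 of all genes, 31.5%. Chance gives 20% for 2 against 3 without ties. The 10 splits of this table, which holds identical values, gave 6.24% on average, and the splits other than the real one 1.43% to 7.59%. Each of those puts a knockout array in a group with a wild-type array, while wild-type arrays lie closer to each other than the knockout arrays do. The other splits are therefore no measure of chance for the real one, and the 31.5% cannot be weighed against their shares. The change and the wild-type level had Pearson r = -0.63 across genes, which are not independent replicates, but the change itself holds the wild-type level. With the level taken from a wild-type array left out of the change, r was -0.59 to -0.64, and with wild-type arrays in place of knockout it was -0.0052 to 0.15. The 3 wild-type values were identical in 39.1% of genes, so an array left out can still share its value with the change. Wild-type pairs differed with a standard deviation of at most 0.182, and a knockout and a wild-type array with at least 0.371. Wild-type arrays therefore do not match the knockout arrays as a control. Of the rises, 271 of 309 started below the wild-type median, and of the falls, 377 of 435 started above it. Receptor genes of smell and pheromone sensing made up 73 of the 309 rises and 3 of the 435 falls, at 5.99% of the genes tested.

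**Figure D2:**
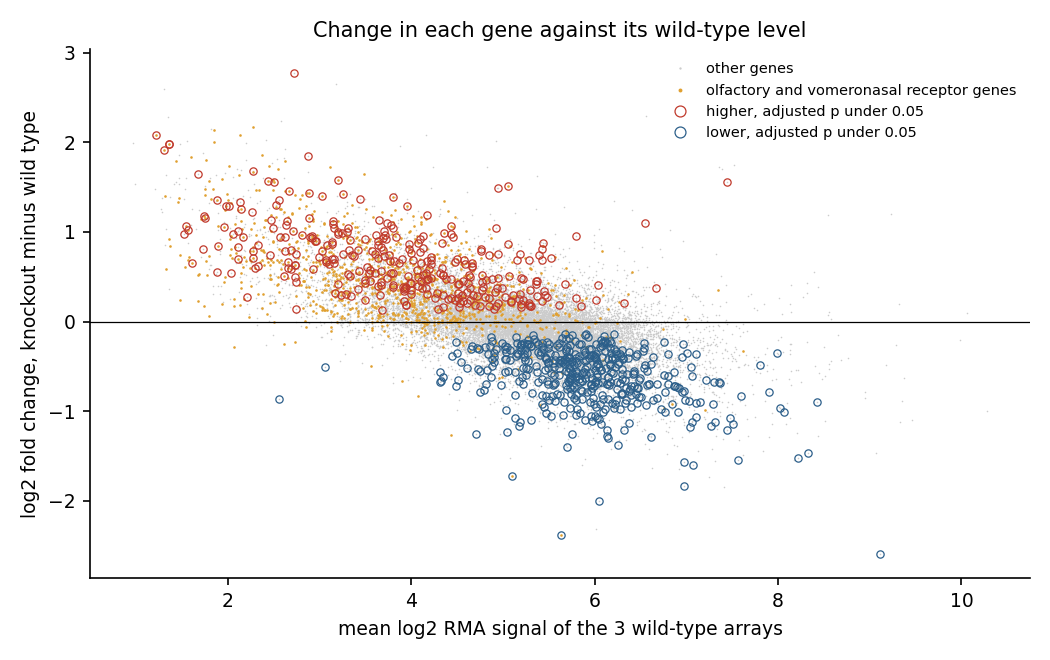
Log2 fold change of each gene, knockout minus wild type, against its mean log2 RMA signal on the 3 wild-type arrays, with olfactory and vomeronasal receptor genes in yellow and genes past adjusted p 0.05 circled in red (309 higher) or blue (435 lower). Rises lie at low and falls at high wild-type levels.

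The counts moved with the scaling and with the array left out. Cyclic loess and the run as a block each left 0 genes in limma, with 3919 and 3829 genes at an unadjusted p under 0.05. Centring each array on its median gave 343 higher and 292 lower, so that 54.0% of the calls were rises in place of 41.5%, and arrays centred and scaled gave 90 higher and 68 lower. Without wild type 3, 4 or 6 there were 0 genes, with 2458, 2312 and 2434 at an unadjusted p under 0.05. Without knockout 2 there were 3913 higher and 3600 lower, and without knockout 5 there were 3930 higher and 6069 lower, with the spread then taken from wild type alone.

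The arrays differed in their likeness to each other. Across genes the wild-type arrays correlated at 0.984 to 0.993, knockout 5 with wild type at 0.903 to 0.927, knockout 2 with wild type at 0.814 to 0.837, and the knockout arrays with each other at 0.803. The first principal component held 64.5% of the variance and set knockout 2 apart, and the second held 29.0% and set knockout 5 apart. The standard deviation of the gene values was 0.802 in knockout 2, 0.906 in knockout 5 and 0.991 to 1.02 in wild type. Wild type 3, the wild-type array of run 1, correlated at 0.985 and 0.984 with wild types 4 and 6 of run 2.

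Cartilage matrix genes were lower in knockout for 17 of 25 measured members, with 2 falls past the threshold and 23 that did not pass. Comp, a matrix protein that binds collagen fibrils, fell from 6.23 to 5.82 (-0.41, SE 0.038, adjusted p = 0.0327), and Col9a3, a chain of the collagen on the surface of type II fibrils, fell from 7.06 to 6.46 (-0.61, SE 0.067, adjusted p = 0.0422). Both changes shrank after cyclic loess, to -0.22 for Comp (adjusted p = 0.163) and -0.34 for Col9a3 (adjusted p = 0.181), and were -0.19 and -0.27 with arrays centred and scaled. With p adjusted over the list alone, 3 genes fell. The list's median change was -0.21, and camera gave adjusted p = 0.105, with adjusted p = 0.683 with an estimated correlation. The median was -0.20 within run 1 and -0.0077 within run 2, and adjusted p = 0.124 with the run as a block. Among random lists of the same wild-type levels the median lay at the 20.7th percentile, and it was -0.00088 after cyclic loess and 0.046 with arrays centred and scaled.

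Chondrocyte transcription factors held 1 fall among 12, that of Sox9, and a median change of -0.076, which turned to 0.046 after cyclic loess. No gene passed the threshold among 14 hypertrophic chondrocyte genes or 20 osteoblast and osteocyte genes, where Alpl, the alkaline phosphatase of mineralising tissue, had -0.25 (adjusted p = 0.117). Matrix proteases and their inhibitors held 1 fall among 26, that of Mmp19 (-0.32, SE 0.026, adjusted p = 0.0276). Collagen receptors held 1 rise among 11, that of the integrin chain Itga11 (0.29, SE 0.027, adjusted p = 0.0323), while Itga10 was at -0.44 (adjusted p = 0.0553). The wild-type values of Itga11 were identical, as were those of Egr1, Id2, Rps20, Ms4a2 and Cdh19, named below. The standard errors of these genes rest on the knockout arrays and limma's moderation. The 3 wild-type arrays held only 2 distinct values for Sox9, Comp and Mmp19, and for Gli1, Cidec, Ckb, Nefl and Pygm, named below. The standard errors of that second set rest in part on identical values and do not measure the spread between mice. Fibrous layer and tendon genes held 1 fall among 25, that of Egr1, which the immediate-early list holds too. Of them 21 were lower, with a median of -0.18 (-0.35 within run 1 and -0.0086 within run 2, camera adjusted p = 0.105, or adjusted p = 0.761 with an estimated correlation), at the 38.5th percentile of random lists of the same wild-type levels.

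Signalling lists held single calls. In the Notch and Hedgehog list the Hedgehog target Gli1 fell from 6.42 to 5.84 (-0.58, SE 0.025, adjusted p = 0.015), and in the Wnt list the receptor Fzd1 fell from 5.97 to 5.23 (-0.74, SE 0.053, adjusted p = 0.0236). Among 27 genes of the TGF-beta and BMP pathway, Id2, an inhibitor of helix-loop-helix factors, rose from 4.00 to 4.31 (0.31, SE 0.03, adjusted p = 0.0344), while the BMP antagonist Nog was at -0.98 (adjusted p = 0.111). Egr1 was the 1 fall among 25 immediate-early genes (-0.41, adjusted p = 0.0423), of which 20 were lower, with a list median of -0.20 and camera adjusted p = 0.0799. That p was 0.625 with an estimated correlation, as an adjusted p, and 0.0944 with the run as a block, and the median was -0.16 within run 1 and -0.068 within run 2. After cyclic loess the median was -0.047, with arrays centred and scaled it was -0.0026, and it lay at the 40.0th percentile of random lists of the same wild-type levels.

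In the oxidative phosphorylation list 2 of 31 genes fell, and 6 fell with p adjusted over the list alone. Ndufs3, a subunit of respiratory complex I, fell from 5.86 to 5.20 (-0.66, SE 0.031, adjusted p = 0.0157), and Sdhb, the iron-sulfur subunit of complex II, fell from 5.96 to 4.91 (-1.05, SE 0.125, adjusted p = 0.0465). The list's median was -0.10, with 0 within run 1 and -0.019 within run 2. It was -0.012 after cyclic loess and 0.0085 with arrays centred and scaled. Camera gave adjusted p = 0.202, or adjusted p = 0.625 with an estimated correlation, and fry gave adjusted p = 0.00042. Among 26 ribosomal proteins Rps20 fell by 0.18 (adjusted p = 0.0315), but its change was -0.046 after cyclic loess (adjusted p = 0.664) and -0.026 with arrays centred and scaled (adjusted p = 0.816). The cell cycle, inflammation, interferon, unfolded protein and hypoxia lists held no call, with medians of 0, -0.028, 0.024, -0.13 and -0.15. For unfolded protein genes the median was -0.15 within run 1, -0.024 within run 2, -0.095 after cyclic loess and -0.00050 with arrays centred and scaled. For hypoxia genes it was -0.30 within run 1, 0 within run 2, 0.0069 after cyclic loess and 0.028 with arrays centred and scaled. The inflammation list had a camera direction of up beside its median below 0, and the hypertrophic list had a mean of 0.0026 beside its median of -0.036.

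With camera at the preset correlation, 0 of the 36 lists passed, 10 had an unadjusted p under 0.05, and fry passed 6. The lowest adjusted p, 0.0799, was shared by the immediate-early list and the sex-linked list, and with an estimated correlation the lowest was 0.625. Of 713 different genes on the lists, 5 rose and 14 fell. After cyclic loess these 19 genes kept their direction, none passed (lowest adjusted p = 0.052), and 8 had changes smaller by over 1.5 times. These 8 were Sox9, Comp, Col9a3, Gli1 (-0.39), Id2 (0.18), Rps20, Cdh19 (0.069) and Uty (0.52). With arrays centred and scaled 4 of the 19 passed.

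No list of markers of other tissues that dissected cartilage can hold passed camera, and for several of them the knockout arrays lay on opposite sides of the average. On knockout 2 the mean deviation from the average of the 5 arrays was -0.39 for osteoclast genes, -0.22 for osteoblast genes, -0.29 for smooth muscle genes and -0.17 for skeletal muscle genes, and on knockout 5 it was 0.057, 0.13, 0.10 and -0.077. B cell genes stood 0.14 and 0.093 above the average on knockout 2 and 5, and their median change was 0.18 (camera adjusted p = 0.105, or adjusted p = 0.625 with an estimated correlation), with 13 of 19 genes higher and no single gene past the threshold. The B cell median was 0.36 within run 1 and 0 within run 2, 0.20 after cyclic loess and 0.25 with arrays centred and scaled. It lay at the 99.7th percentile of random lists of the same wild-type levels, and that of T and NK cell genes (0.087) at the 96.4th, over 36 lists looked at. Macrophage, neutrophil and mast cell genes were at 0.14, 0.14 and 0.16 on knockout 5 and at -0.027, -0.034 and -0.0076 on knockout 2.

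Markers passed the test in the mast cell, adipocyte, skeletal muscle, osteoclast and nerve lists. On the sex-linked list, which marks no tissue, 1 gene passed. Ms4a2, a chain of the mast cell IgE receptor, rose from 3.31 to 4.30 (1.00, SE 0.068, adjusted p = 0.0226). Fcer1a, another chain of that receptor, was at 0.56 (adjusted p = 0.127), while the mast cell gene Tpsb2 was at -0.44 (adjusted p = 0.365), with -0.68 within run 1 and -0.19 within run 2. Cidec, a lipid droplet protein of fat cells, fell from 6.09 to 5.08 (-1.01, SE 0.071, adjusted p = 0.0231). Pygm, the glycogen phosphorylase of muscle, fell from 4.87 to 4.25 (-0.62, adjusted p = 0.0442), and Ckb, a creatine kinase on the osteoclast list, fell from 7.27 to 6.10 (-1.17, adjusted p = 0.0299). On that list Ctsk was at 0.62 (limma's adjusted p = 0.171) and Itgb3 at -0.41 (limma's adjusted p = 0.0725). Of its 15 genes 4 were higher and 10 lower. In the nerve list the neurofilament gene Nefl fell by 0.62 (adjusted p = 0.0125) and Cdh19 rose by 0.50 (adjusted p = 0.0211), though quantile normalisation turned Cdh19 to -0.00076. On the sex-linked list the Y-linked gene Uty rose from 2.57 to 3.52 (0.94, adjusted p = 0.0308) and, with no call of detection above background, this does not show expression from the Y chromosome or the sex of a mouse. Endothelial (median -0.18), erythroid, synovial, epithelial, brain and T cell lists held no call. The endothelial median was -0.14 within run 1, 0 within run 2, -0.059 after cyclic loess and -0.021 with arrays centred and scaled.

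The 38 genes in the region around Ddr1 held no call, with 28 of them lower and a median change of -0.083 (-0.13 within run 1 and -0.045 within run 2), which was 0.017 after cyclic loess. Abcf1 was lowest in p there, at -0.26 (adjusted p = 0.0602).

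**Figure D3:**
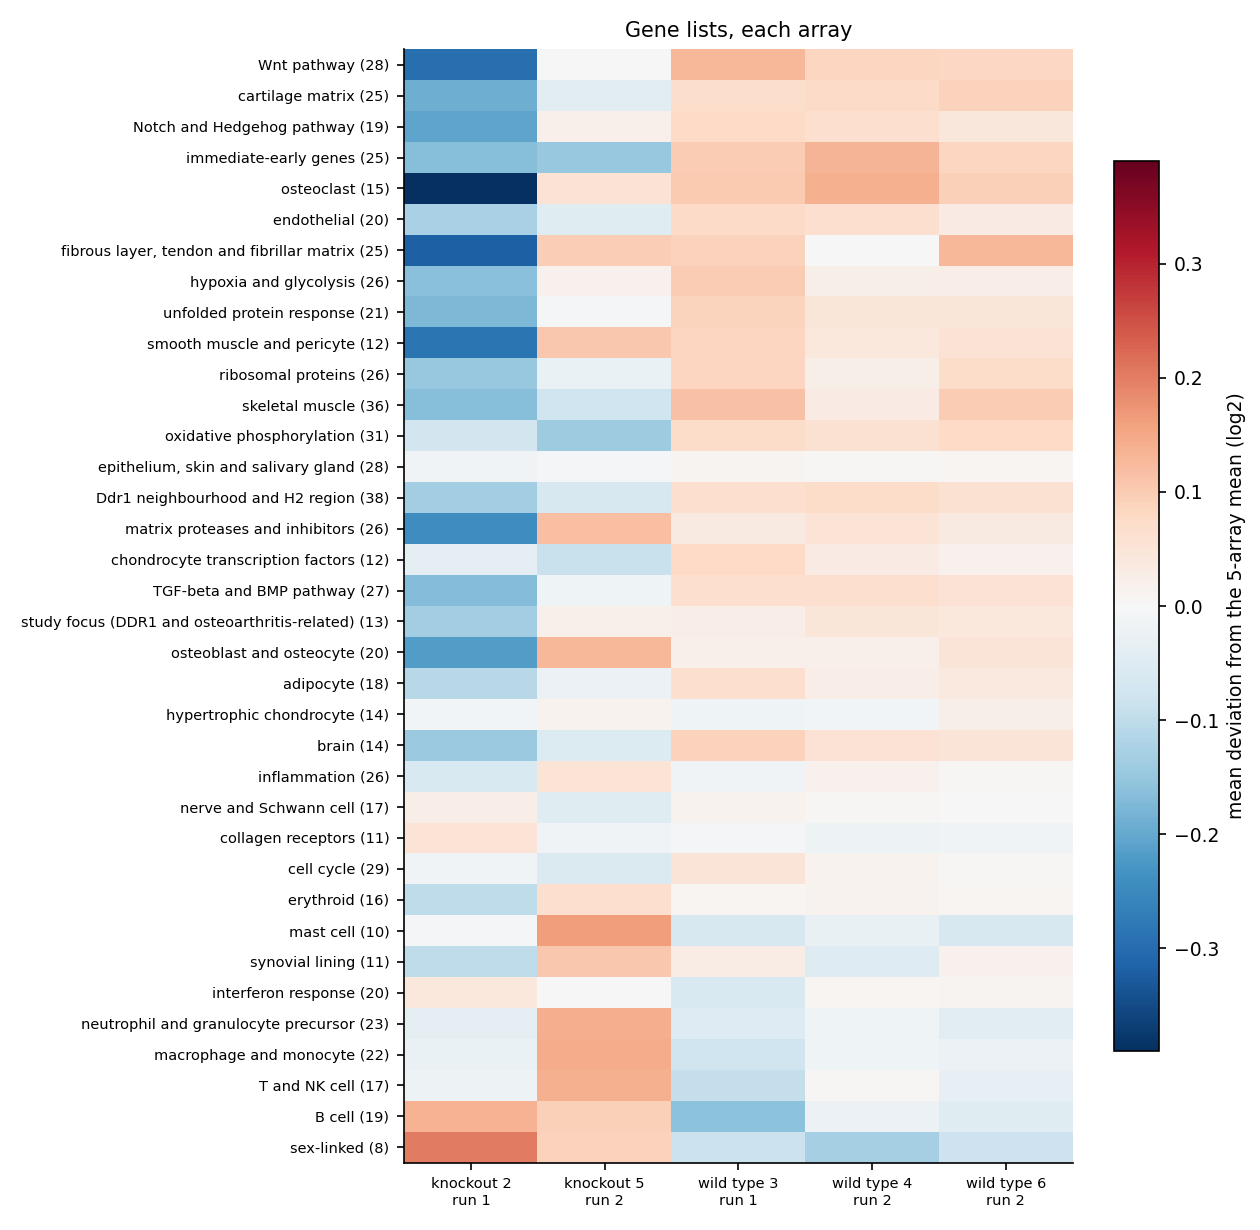
Mean deviation of each gene list from its average over the 5 arrays, in log2 units, with arrays in columns, lists in rows ordered by median change and the number of measured genes in parentheses. Knockout 2 holds the lowest value, -0.39 for osteoclast genes, and the sex-linked and B cell lists are above the average on both knockout arrays.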

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

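All tests of explanations in this part were chosen only after the result was seen, except the count of other splits of the arrays, which was planned.

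Rows of the array that the comparison of genes left out also differed between genotypes, above the wild-type level or below it. In the fit over every row, 241 of the 12146 rows with no gene symbol were higher in knockout and 102 were lower at adjusted p under 0.05. Among the 1621 rows with several symbols, 19 were higher and 5 were lower.

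The genes past the threshold went with their wild-type level, with rises at low and falls at high levels. A difference in array run is argued against, because the standard deviation over genes of each knockout array was at most 0.9145 times that of a wild-type array of its own run, while wild-type arrays of run 2 had ratios of 0.983 and above. A narrower signal range on both knockout arrays may account for part of the pattern: over rows with no gene symbol, which made none of these calls, the standard deviations were 1.55 and 1.75 in knockout against at least 1.90 in wild type. An effect of the knockout on the genes that fell stays open, since cyclic loess moved their median change from -0.57 to -0.44 and no call passed, while the median standard error of the 744 genes rose from 0.0453 to 0.0744. Knockout and signal range cannot be told apart for these genes, because both go with the same 2 arrays, and the lower likeness of these arrays to wild type (correlations of 0.814 to 0.927) can tie change to level on its own.

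The knockout arrays were unlike each other, with a correlation across genes of 0.803. A run effect that is alike in both genotypes is argued against as the only reason, as wild-type arrays of different runs correlated at 0.984 or more. That rests on wild type 3, the only wild-type array of run 1, whose value equalled another array's in 59.8% of genes. The knockout arrays are in different runs, so a run effect on knockout arrays only cannot be told apart from other differences between them. Different tissue content of the knockout samples stays open. Receptor genes differed with a standard deviation of 0.703 against at most 0.283 between wild-type arrays, which does not decide it. Their median wild-type level was 3.93 against 5.16 over all genes, and at such low levels the test could not argue against tissue content. A difference in array signal and a difference between the knockout mice stay open too, and neither was tested.

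The 5 arrays make 10 splits into groups of 2 and 3, too few for a share under 0.05. The real split gave 744 genes and the highest of the other splits 0 in limma, where the split by run had 314 genes at an unadjusted p under 0.05. Every other split puts a knockout array in a group with a wild-type array. The knockout arrays are less like wild type, so this widens the spread within groups, whatever the reason for the lower likeness. The count of 0 therefore does not decide between the genotype and other reasons for that lower likeness.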

How the results depend on the processing

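Cyclic loess, arrays centred and scaled, and the restrictions on genes with identical values were chosen after seeing the data, and all other alternatives were planned. Mice could not be paired by replicate number, as the groups share none, and matching by array run entered as the block and as differences within each run. The counts of 309 higher and 435 lower genes were 0 and 0 with the run as a block, arrayWeights, quantile normalisation or cyclic loess, with 3829, 1917, 3761 and 3919 genes at an unadjusted p under 0.05 in limma. They were 111 and 163 with an ordinary test without moderation, 90 and 68 with arrays centred and scaled, and 654 and 976 at adjusted p under 0.1. Filters left 60 higher genes at a mean level of at least 5 and 80 without genes whose mean lay under 4.76, with 403 and 391 lower. Leaving out an array in turn gave 0 to 3930 higher and 0 to 6069 lower, with 0 without wild type 3, 4 or 6 (2458, 2312 and 2434 genes at an unadjusted p under 0.05), 3913 and 3600 without knockout 2, and 3930 and 6069 without knockout 5. A lone knockout array is assumed there to vary like wild type. Of the 744 genes, 212 had 3 identical wild-type values. Without genes of 1 distinct value there were 254 higher and 328 lower, and 492 of the 744 remained. Among the 2535 genes with 5 distinct values there were 270 higher and 331 lower, of which 170 were among the 744.

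Why calls were lost was not tested, and only sizes and standard errors of the called genes are given here. Of the 744 genes, all kept their direction under the run as a block, as genes whose groups do not overlap must, and 726 kept it under cyclic loess. Under the block their median size went from 0.584 to 0.588 and their median standard error from 0.0453 to 0.0400. Residual degrees of freedom went from 3 to 2, and the lowest adjusted p in limma was 0.0517. Under cyclic loess the median size fell to 0.448 and the median standard error rose from 0.0453 to 0.0744. Median centring and scaling gave 54.0% and 57.0% of calls as rises, against 41.5% as deposited. Over every row of the table, named or not, there were 463 higher and 382 lower, 54.8% rises. No alternative scaling moved the median of all genes by over 0.1, and the filter at a mean level of 5 left a median of -0.12. Lists past the threshold numbered 0 with camera, 2 at adjusted p under 0.1 and 6 with fry, which asks another question, and 0 with each array left out.

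For Ddr1 the change was 0.011 with quantile normalisation, 0.035 with cyclic loess and 0.083 with arrays centred and scaled, and -0.22 to -0.052 with an array left out. For Acan it was 0.043 with the run as a block, 0.043 with quantile normalisation, 0.036 with median centring, 0.068 with cyclic loess and 0.046 with scaling, and -0.59 to 0.52 with an array left out. Quantile normalisation also turned Cdh19 (-0.00076), Ihh (0.022), Il6 (-0.30), Krt8 (0.13) and Mmp13 (0.0013). Cyclic loess turned Col2a1 (0.045), Ihh (0.082), Il6 (-0.20) and Krt8 (0.16). Scaling turned Aqp5 (0.091), Col22a1 (0.014), Col2a1 (0.16), Ihh (0.15), Il6 (-0.027), Krt8 (0.27) and Mmp13 (0.0015), and median centring turned Il1b (0.016) and Itgb1 (0.0066). With an array left out, the change ran from -1.07 to 0.029 for Adamts5, -0.0030 to 0.69 for Col10a1, -0.14 to 0.0091 for Itgb1 and -0.069 to 0.995 for Vegfa. The cause was not tested. Of the 43 named genes past the threshold, the block, arrayWeights, cyclic loess, quantile normalisation and each wild-type array left out lost 43, the ordinary test 35, scaling 26, every row 15, trend and robust 13, median centring 8, knockout 2 left out 6, leaving out genes of 1 distinct value 6 and the mean of a gene's rows 5. No call of detection above background was used here, so how far low signal limits these results is open.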

Other observations

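The observations in this part, including the genes singled out, were chosen only after their values were seen, and none was weighed by a test of an explanation.

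Actb, Hspa8, Rny3 and ND3, which many cells hold in large amounts, had changes of different sign, and none passed limma's test. Actb, the cytoskeletal actin, was at 4.51 and 5.48 in knockout against 6.56 to 6.76 in wild type (-1.64, adjusted p = 0.113). Hspa8, a constitutive chaperone, was at 5.68 and 6.44 against 4.21 to 4.93 (1.45, adjusted p = 0.153), and the small RNA Rny3 at 8.43 and 9.75 against 7.02 to 7.78 (1.73, adjusted p = 0.215). The mitochondrial gene ND3 was at 8.64 and 9.55 against 6.72 to 8.32 (1.70, adjusted p = 0.31). Sparc, a matrix protein of bone and connective tissue, was at 6.37 in knockout 2 and 8.95 in knockout 5, with wild type from 7.11 to 7.70.

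Receptor genes of smell and pheromone sensing had a median change of 0.40, against 0.20 in other genes of the same wild-type level. They made up 23.6% of the rises. Random genes of the same wild-type levels, drawn 10000 times, gave a median of 18.1%, with the middle 95% of draws from 14.2% to 22.3%. The draws took genes as independent of each other, so this interval can be too narrow and does not decide whether receptor genes stand out.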
